A study of Mus musculus with 8 samples.

How the data were processed

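Total RNA was measured in whole brain and whole uterus of pregnant C57BL/6J mice on day 4 of gestation, with 4 libraries from brain and 4 from uterus, each made from 1 animal without pooling. The library kit was stranded and removed ribosomal RNA. Per the labels, the authors processed the reads with FastQC, HISAT2 version 2.0.3, featureCounts and edgeR on the GRCm38.p5 build. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited table holds raw counts for 19884 Ensembl genes, in whole numbers and with no normalization, and 894 of these genes had 0 counts in all 8 libraries. Of the gene identifiers, 19774 were found in GENCODE M21 on GRCm38, which gave the coordinates, and 98.4% of the table was annotated as protein coding. Bare numbers stood in place of 27 symbols, and 38 entries shared a symbol with another. Coordinates and copies were therefore matched by identifier, while members of the lists, pairs and symbol groups were found by symbol.

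Library totals ran from 35394603 to 47790178 counts. A total of 3 counts was taken as the limit that a count of 0 allows, which is 0.0692 to 0.0810 CPM (counts scaled to the library total) for a single library. Folds against an organ with 0 counts are lower bounds against 3 counts over its 4 libraries together. Where the lower organ held 1 to 3 counts, the ratio is given with its exact Poisson 95% interval. Reads without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only. CPM values use library sizes scaled by TMM, whose factors were 0.907 to 0.924 in brain and 1.07 to 1.11 in uterus.

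Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9, and BLAST+ 2.17.0. Genes with low counts were removed with filterByExpr by organ, which left 16074 genes. Uterus was compared with brain by the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05, and against a 2-fold change by glmTreat on the same fit. Log2 fold changes are uterus over brain, so positive values mean higher in uterus. Their errors, given as SE, are the unshrunken log2 fold change divided by the square root of its F statistic. For folds that rest on few counts they can be too small. Aqp4, at -12.33 ± 0.25 with 8 counts in uterus, moved to -13.72 without uterus library 4. A gene was taken as detected at 1 CPM or more in all 4 libraries of an organ, and as restricted to that organ when it was also under 0.1 CPM in all 4 libraries of the other. Like levels were called where the limma-voom 95% interval of the log2 fold change lay wholly within -0.5 to 0.5. Spread between animals is the common biological coefficient of variation of edgeR within an organ.

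The tests, the 40 gene lists, the 36 ligand and receptor pairs and the rule for naming genes were fixed before the data were examined. Lists were tested with limma camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, two-sided and adjusted over all lists. Beside it stand camera with an estimated correlation, the fry test, and per-gene counts from edgeR over all genes and adjusted over the list alone. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The naming rule took the 10 genes with the largest change in each direction among those past the 2-fold test, at 50 CPM or more in the higher organ and with no overlap between the organs' libraries, leaving out unnamed gene models. From each list it took the 3 called members with the largest change at 1 CPM or more, and up to 2 called members at 10 CPM or more that went against the list's median. It also took the 5 most abundant genes at like levels, 18 genes of prior interest in reproduction that had an entry here, and per organ the 5 genes at 20 CPM or more that varied most between animals. The rule gave 169 genes, and other genes are named only where a count or a pair of ligand and receptor needs them.

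No term for animal was fitted, because the labels do not say that a replicate number marks the same mouse in both organs. Alternatives were RLE, upper-quartile and library-size scaling, removal of the 20 top genes and the mitochondrially encoded genes, other filters for low counts, a block for replicate number, DESeq2, limma-voom, an adjusted threshold of 0.01, other detection limits, bounds of 0.3 for like levels, a prior count of 0.5, and leaving out each library in turn. A fit with only brain libraries 2 to 4 and uterus libraries 1 and 3 was added after the data were seen. Near-identical copies of transcripts were searched with BLAST+ in the annotated transcripts, at 98% identity over at least 150 nt, or 100 nt for mitochondrially encoded genes.

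The procedure was tested on simulated counts with a dispersion of 0.02 in both organs and 200 changed genes, drawn from genes with a mean of 100 counts or more. The real organs differed in most genes and in their spread (9.07% in brain, 16.4% in uterus). The rates below therefore need not hold for the real data, least of all for genes with few counts. The quasi-likelihood test recovered 72.0% of 50 genes changed 1.5-fold and 100% of those changed 2-fold, 4-fold and 8-fold, with 4.12% of calls false. The 2-fold test called 0% of genes changed 1.5-fold or 2-fold and 100% of those changed 4-fold or 8-fold. DESeq2 recovered 92.0% of all changed genes. Like levels were called for 73.4% of unchanged genes and 0% of changed genes, whose simulated changes all lay outside the bounds of -0.5 to 0.5. Camera called the changed list and 0 others. When most genes changed, the median error of the log2 fold change was -0.26 with the scaling used here. Some genes are counted in the totals of tests and lists but not reported here, among them 3 of the values that stood apart from the other libraries of their organ.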

Results

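RNA was sequenced from whole maternal brain and whole uterus of mice on day 4 of gestation, when the uterus prepares to receive the embryo, with 4 libraries per organ. Brain libraries held 40115616 to 47790178 counts (mean 45389442, n = 4) and uterus libraries 35394603 to 40254254 (mean 37658734, n = 4). Mitochondrially encoded genes took 5.16 ± 0.580% of brain counts and 4.37 ± 1.13% of uterus counts (SD, n = 4), and the 20 most abundant genes took 7.78 ± 0.340% and 8.28 ± 0.861%. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.982 to 0.993 within an organ and 0.536 to 0.558 between organs. The first principal component separated the organs with 96.5% of the variance, against 1.02% for the second. Gene values below are mean CPM ± SD over n = 4 libraries, and log2 fold changes are uterus over brain ± SE.

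The comparison of the organs asks which genes the uterus and the brain of the same stage of pregnancy each express above the other. Hoxa10, a HOX transcription factor of the uterus (ENSMUSG00000000938, chromosome 6, 52231197 to 52240854), reached 364 ± 33.4 CPM in uterus and 0.0234 ± 0.0270 in brain, a log2 fold change of 13.71 ± 0.23 (adjusted p = 9.4e-12). Col3a1, which encodes a fibrillar collagen (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), stood at 5140 ± 542 CPM against 7.67 ± 0.868. Snap25, a protein of the synaptic vesicle fusion complex (ENSMUSG00000027273, chromosome 2, 136713453 to 136782428), stood at 2412 ± 65.3 CPM in brain against 0.553 ± 0.5501 in uterus, a log2 fold change of -12.06 ± 0.51, or -13.05 without uterus library 4, which held 1.38 CPM.

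Of 16074 genes tested, 13989 (87.0%) differed between the organs by edgeR, 6988 higher in uterus and 7001 higher in brain. Against a 2-fold change, 7922 genes (49.3%) passed, 3781 higher in uterus and 4141 higher in brain. Among the 156 genes of the naming rule that were called, 151 had the 4 libraries of 1 organ above all 4 of the other; the exceptions were Wnt4, Ptgs2, Tac2, Car3 and Hba-a2. Scaling by library size alone moved the median log2 fold change of all tested genes from 0.012 to 0.27, and upper-quartile scaling also gave 0.27, so small changes depend on the scaling. So does the balance of the organs: 8182 genes were higher in uterus and 5966 in brain with upper-quartile scaling, and 8179 and 5949 with library sizes. Against a 2-fold change the balance turned, to 4387 in uterus and 3646 in brain with upper-quartile scaling and to 4390 and 3639 with library sizes.

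**Figure D1:**
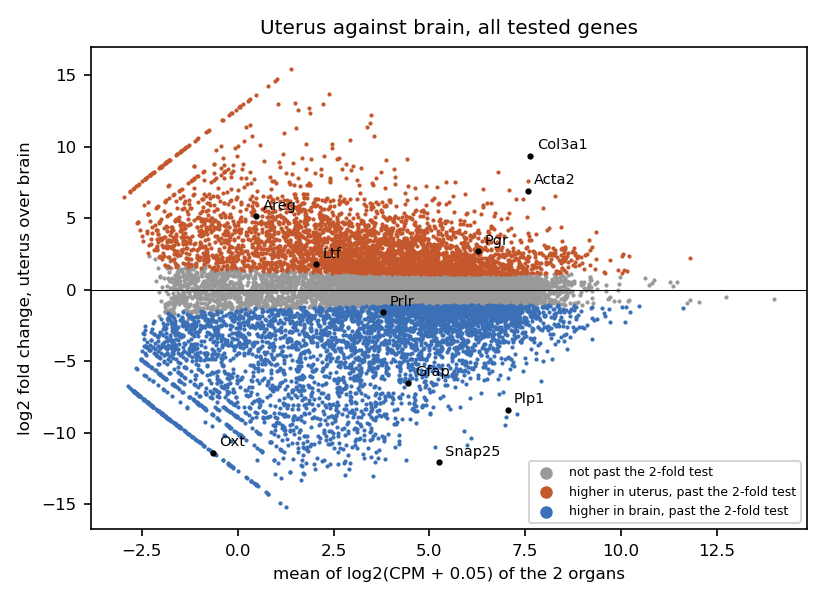
Each point is 1 of 16074 tested genes, with the mean of the log2 CPM values of both organs on the x axis and the log2 fold change of uterus over brain on the y axis. Orange and blue points are the 3781 and 4141 genes past the 2-fold test, the straight edges are genes with few or 0 counts in 1 organ, and black points are labelled genes.

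The 10 largest changes toward uterus held 4 genes with 0 counts in brain. They were Spink1, a trypsin inhibitor of secretory glands (ENSMUSG00000024503, chromosome 18, 43728082 to 43737557), at 136 ± 142 CPM, Hoxd9 at 83.1 ± 8.82, Hand2 at 76.7 ± 13.3 and Hoxd11 at 59.6 ± 6.82. These levels were at least 7522-fold, 4596-fold, 4244-fold and 3297-fold higher than in brain. Hand2 encodes a stromal transcription factor that progesterone induces (ENSMUSG00000038193, chromosome 8, 57320983 to 57324633). The calcium-binding protein gene S100g stood at 274 ± 71.5 CPM, with a log2 fold change of 13.01 ± 0.38, or 13.80 without brain library 4. Osr2, Prss28 and Hoxa9 had 1 to 3 brain counts, and their ratios were 10795 (95% interval 2988 to 89136), 12576 (2257 to 496730) and 7171 (2454 to 34775). These counts lay in 1 brain library for each gene, and the fitted log2 fold change, which is no bound, moved from 13.08 to 15.39 for Osr2 without brain library 2 and from 12.59 to 15.38 for Hoxa9 without brain library 3. The serine protease genes Prss28 and Prss29 were uneven between animals, at 75.8 ± 101 and 183 ± 256 CPM. Leaving out uterus library 2 lowered the fitted log2 fold change of Prss28 from 13.03 to 11.54 (14.60 without brain library 2), that of Prss29 from 12.72 to 11.05 and that of Spink1, whose fitted value is no bound, from 15.46 to 14.46. Limma-voom did not call Spink1, Prss28 or Prss29.

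Toward brain, 5 of the 10 largest changes were genes with 0 counts in uterus. Car10, a carbonic anhydrase-related protein gene, stood at 116 ± 2.62 CPM, Sst, the gene of somatostatin (ENSMUSG00000004366, chromosome 16, 23889573 to 23890958), at 92.6 ± 5.75, and Gabra5, a GABA-A receptor subunit gene, at 59.8 ± 1.79. Resp18 and Nrsn2 stood at 60.5 ± 4.97 and 56.0 ± 2.88 CPM. The 5 levels were at least 6351-fold, 5078-fold, 3283-fold, 3319-fold and 3073-fold above uterus in that order. Eef1a2, a translation elongation factor gene of neurons and muscle, reached 894 ± 49.8 CPM, with a log2 fold change of -13.04 ± 0.34, or -14.29 without uterus library 4. Rph3a, a synaptic vesicle protein gene, reached 464 ± 28.5 CPM, with a log2 fold change of -12.97 ± 0.27, or -13.66 without uterus library 2. The ratios of brain to uterus for Fat2, Htr2c and Epha10, which had 1 or 2 uterus counts, were 12761 (95% interval 3533 to 105370), 14207 (2550 to 561130) and 11280 (2025 to 445540). These counts lay in 1 uterus library for each gene, and the fitted log2 fold change, which is no bound, moved from -13.32 to -15.65 for Fat2 without uterus library 1, from -13.21 to -14.81 for Htr2c without uterus library 3 and from -12.88 to -14.45 for Epha10 without uterus library 4.

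Camera with the preset correlation called 22 of the 39 lists that had a tested gene. With an estimated correlation camera called 0 of them, with 9 at an unadjusted p under 0.05, and fry called 36. Per-gene counts below are from edgeR over all genes tested, and those adjusted over the list alone were the same except where given. Each list's median kept its sign under RLE, upper-quartile and library-size scaling, except that of the reference genes.

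Epithelial genes of the uterus stood well above brain. Of 17 tested genes of the list for the receptive epithelium, 16 were higher in uterus and 1, Calca, did not pass (4.20 against 3.12 CPM). Their median log2 fold change was 6.28 (camera adjusted p = 4.0e-05, and adjusted p = 0.0807 with an estimated correlation). Beside progesterone-induced genes the list holds epithelial genes such as Epcam, Cdh1 and Krt8. No other state of the uterus was measured, so these counts do not tell receptivity or hormone action from uterus in general. Ihh, the hedgehog ligand that signals from epithelium to stroma, stood at 71.7 ± 14.2 CPM against 0.338 ± 0.165 (7.70 ± 0.26). Areg, an EGF receptor ligand (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432), stood at 7.49 ± 4.24 against 0.211 ± 0.0813 (5.13 ± 0.51), and Cyp26a1, a retinoic acid-degrading enzyme gene, at 139 ± 63.8 against 0.234 ± 0.110 (9.19 ± 0.56). Epcam, an epithelial adhesion gene, differed by 8.46 ± 0.14, and Acod1, the itaconate-producing enzyme gene, by 10.17 ± 0.23, or 10.82 without brain library 4.

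Of 11 tested gland genes, 9 were higher in uterus, while Wnt7a (25.9 against 23.8 CPM) and Wnt7b (12.7 against 27.7) did not pass, with a median of 6.21 (camera adjusted p = 0.0135; adjusted p = 0.204 with an estimated correlation). Lif, the cytokine of glands needed for implantation in mice (ENSMUSG00000034394, chromosome 11, 4257557 to 4272514), stood at 40 ± 9.27 CPM in uterus against 0.536 ± 0.211 in brain (6.21 ± 0.27, adjusted p = 5.2e-09). Foxa2, a transcription factor of the gland epithelium, stood at 10.9 ± 2.40 against 0.196 ± 0.116 (5.76 ± 0.33). Cxcl15 had 0 counts in brain and 22.1 ± 5.18 CPM in uterus, at least 1220-fold higher. The gland list was also the most uneven of the uterine lists between animals, with mean deviations on the log2 scale of -0.18, 1.03, 0.46 and -1.30 in uterus libraries 1 to 4.

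Of 10 tested oestrogen-induced epithelial genes, 7 were higher in uterus and 1 in brain, with a median of 5.90 (camera adjusted p = 0.0130; adjusted p = 0.186 with an estimated correlation). Pigr, the receptor gene that carries immunoglobulins across epithelia, stood at 46.7 ± 18.6 CPM (9.53 ± 0.52, or 10.36 without brain library 4). Padi1, a citrullinating enzyme gene, stood at 33.8 ± 33.2 (8.16 ± 1.06, or 7.29 without uterus library 4), and it was not called by limma-voom. Lcn2 (9.22 against 3.97 CPM) and Ltf, the lactoferrin gene, did not pass. Ltf was 7.55 ± 4.55 in uterus and 2.20 ± 3.29 in brain (1.77 ± 0.89, adjusted p = 0.0855), and it passed without brain library 2 (3.77), which held 7.13 CPM, with a block for replicate number (2.48) and with limma-voom (2.73). The member higher in brain, Wnt4, was 15.9 ± 2.37 CPM there and 11.5 ± 2.46 in uterus (-0.47 ± 0.17). That call ended under upper-quartile (-0.21) and library-size (-0.20) scaling and without brain library 3 (-0.42), brain library 4 (-0.40) or uterus library 1 (-0.44).

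Stromal, muscle and matrix genes made up another part of the uterine profile. Of 15 tested genes of stroma and decidualization, 13 were higher in uterus and 2, Fgf9 and Alpl, in brain, with a median of 3.67 (camera adjusted p = 0.000933; adjusted p = 0.186 with an estimated correlation). Hoxa11 stood at 175 ± 14.5 CPM (12.36 ± 0.22, or 13.15 without brain library 3), while Fgf9, a fibroblast growth factor gene, stood at 26.9 ± 0.900 in brain and 5.95 ± 2.31 in uterus (-2.18 ± 0.27). All 9 tested posterior HOX genes were higher in uterus, with a median of 12.36, or 11.69 with genes at 0 counts set to their bounds (camera adjusted p = 0.000131; adjusted p = 0.186 with an estimated correlation). All 15 genes of collagens and matrix were higher in uterus, with a median of 5.39 (camera adjusted p = 5.1e-06; adjusted p = 0.186 with an estimated correlation). Among them Col1a1 reached 2687 ± 343 CPM against 13.7 ± 0.958 (7.61 ± 0.13), and Mmp2, a matrix-degrading protease gene, 434 ± 33.7 against 3.01 ± 0.433 (7.17 ± 0.12).

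Of 14 smooth muscle genes, 13 were higher in uterus and 1 in brain, with a median of 5.12 (camera adjusted p = 9.1e-05; adjusted p = 0.189 with an estimated correlation). The contractile genes Actg2, Cnn1 and Des stood at 547 ± 68.3, 489 ± 68.9 and 689 ± 120 CPM, with log2 fold changes of 11.64 ± 0.20, 9.13 ± 0.15 and 7.53 ± 0.17. Casq2, a calcium store protein gene, was 10.7 ± 0.417 CPM in brain and 7.16 ± 1.88 in uterus (-0.58 ± 0.17), a call that ended under upper-quartile and library-size scaling (-0.32 in both) and with only brain libraries 2 to 4 and uterus libraries 1 and 3 (-0.24). All 16 cell cycle genes were higher in uterus, with a median of 4.66 (camera adjusted p = 4.0e-05; adjusted p = 0.255 with an estimated correlation). Mki67, a marker of dividing cells, was 234 ± 67.4 CPM against 3.88 ± 1.81 (5.93 ± 0.35), Top2a 295 ± 72.8 against 3.76 ± 1.29 (6.31 ± 0.28), Cdk1 66.6 ± 17.7 against 0.833 ± 0.564 (6.35 ± 0.39) and Aurkb 29.9 ± 7.86 against 0.452 ± 0.137 (6.05 ± 0.28). Mean deviations of the cell cycle list in uterus libraries 1 to 4 were 0.070, 0.17, -0.45 and 0.21.

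Steroid receptors were split between the organs. Esr1, the oestrogen receptor alpha gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), was 344 ± 28.4 CPM in uterus and 5.37 ± 0.352 in brain (6.00 ± 0.09). Pgr, the progesterone receptor gene (ENSMUSG00000031870, chromosome 9, 8899833 to 8968611), was 195 ± 48.1 in uterus and 30.5 ± 4.56 in brain (2.68 ± 0.18), and the oestrogen-regulated gene Greb1 was 34.5 ± 23.0 and 2.84 ± 0.637 (3.60 ± 0.43). Nr3c2, the mineralocorticoid receptor gene, was 51.4 ± 2.996 in brain and 3.05 ± 0.571 in uterus (-4.07 ± 0.12). Of the 17 receptors and cofactors, 7 were higher in uterus and 10 in brain; the median was -0.46 and the mean 0.13, and the list was not called (camera adjusted p = 0.601; adjusted p = 0.762 with an estimated correlation).

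Prostaglandin genes were mostly higher in uterus, with 12 of 17, against 4 higher in brain and 1, Ptger1, that did not pass (2.22 against 1.91 CPM). Their median was 2.32 (camera adjusted p = 0.0175; adjusted p = 0.204 with an estimated correlation). The receptor genes Ptger2 and Ptger4 were 52.9 ± 18.8 and 59.8 ± 3.22 CPM in uterus (6.25 ± 0.33 and 4.84 ± 0.13). Ptgds, the prostaglandin D synthase gene, was 733 ± 11.8 in brain against 0.412 ± 0.191 (-10.78 ± 0.21). Ptgs2, the inducible cyclooxygenase gene, was 12.7 ± 3.46 in brain and 6.93 ± 2.64 in uterus (-0.87 ± 0.28, adjusted p = 0.0146). Its call ended under upper-quartile and library-size scaling (-0.61 in both) and without brain library 1 (-0.68).

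Immune and vascular genes were mostly higher in uterus. Of 16 tested leukocyte genes, 13 were higher in uterus, Cd4 was higher in brain, and S100a8 (0.921 against 2.19 CPM) and S100a9 (1.00 against 2.76) did not pass, with a median of 4.91 (camera adjusted p = 0.00455; adjusted p = 0.255 with an estimated correlation). Ncr1, a receptor gene of natural killer cells, was 8.74 ± 0.509 CPM against 0.0657 ± 0.0334 (6.98 ± 0.23), and Gzma, a cytotoxic granule gene with 2 brain counts, was 9.05 ± 4.51, a ratio of 751 (95% interval 208 to 6200). Its counts lay in brain library 1, without which the fitted log2 fold change moved from 9.23 to 11.57. Of 16 interferon and antigen presentation genes, 15 were higher in uterus and 1, Ifit3, did not pass (9.54 against 9.07 CPM), with a median of 2.97 (camera adjusted p = 9.1e-05; adjusted p = 0.322 with an estimated correlation). Nlrc5, an activator of class I genes, was 35.1 ± 2.77 CPM against 1.38 ± 0.565 (4.66 ± 0.23), and the immunoproteasome gene Psmb8 was 42.0 ± 2.02 against 1.78 ± 0.489 (4.56 ± 0.17).

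Of 12 endothelial genes, 10 were higher in uterus and 2 in brain, with a median of 2.63 (camera adjusted p = 0.00217; adjusted p = 0.281 with an estimated correlation). Cdh5 and Pecam1, junction genes of vessels, were 246 ± 25.8 and 271 ± 12.5 CPM in uterus against 19.4 ± 1.16 and 25.2 ± 1.72 (3.66 ± 0.09 and 3.43 ± 0.07). Cldn5, a tight junction gene of the blood-brain barrier, was 40.9 ± 4.22 in brain and 24.3 ± 4.21 in uterus (-0.75 ± 0.12). Flt1, a VEGF receptor gene, was 97.5 ± 2.67 and 75.4 ± 3.89 (-0.37 ± 0.05), and its call ended under upper-quartile (-0.12) and library-size (-0.11) scaling.

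**Figure D2:**
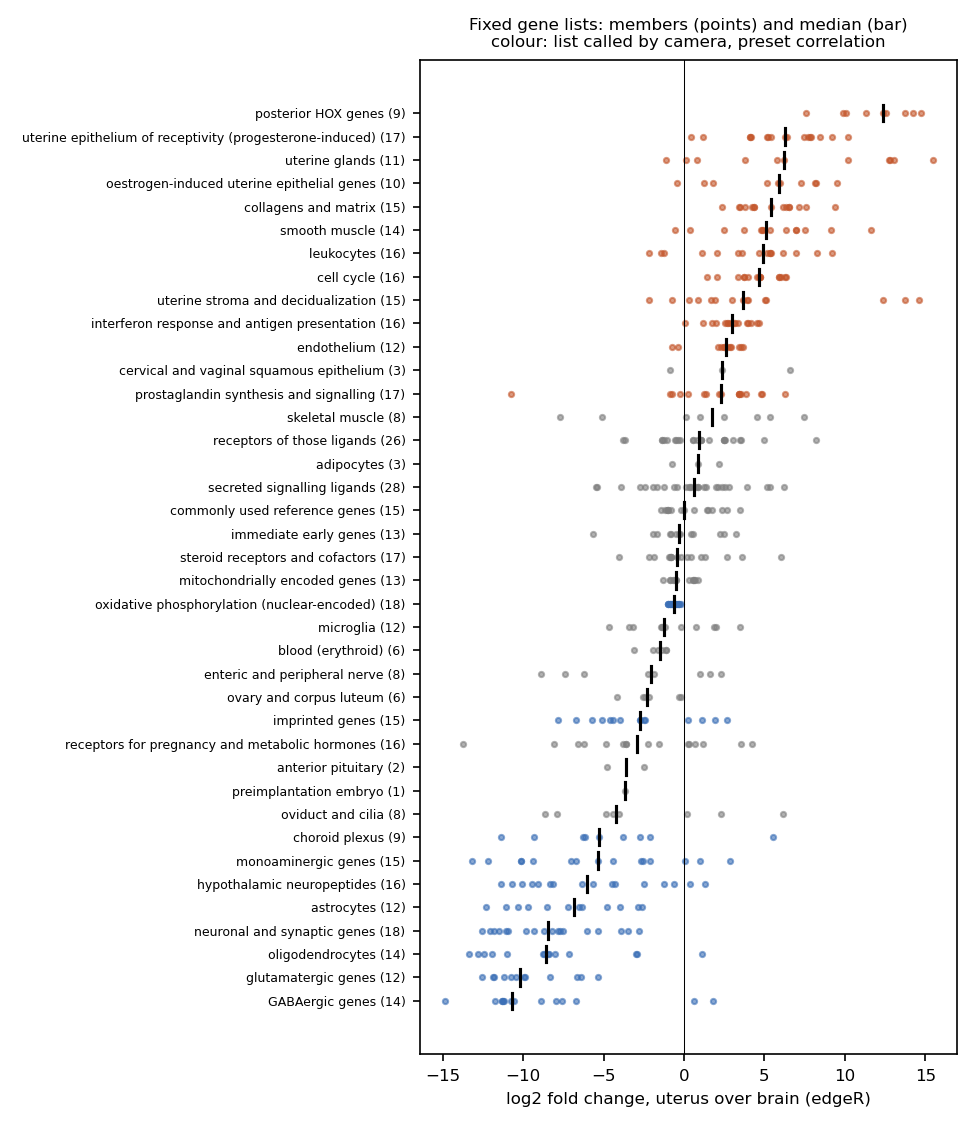
Log2 fold changes of uterus over brain for each tested member (points) of the 39 gene lists, with the number of tested members in brackets and the median as a black bar. Orange and blue lists were called by camera with the preset correlation as higher in uterus or in brain and grey lists were not called, and medians ran from 12.36 for posterior HOX genes to -10.68 for GABAergic genes.

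Neuronal genes marked the brain side. All 18 neuronal and synaptic genes were higher in brain, with a median of -8.46 (camera adjusted p = 6.0e-06; adjusted p = 0.186 with an estimated correlation), and Nefl, a neurofilament gene, was 457 ± 25.3 CPM against 0.0731 ± 0.0650 (-12.55 ± 0.23). All 12 glutamatergic genes were higher in brain, with a median of -10.19 (camera adjusted p = 9.8e-05; adjusted p = 0.186 with an estimated correlation), and Slc17a7, a vesicular glutamate transporter gene, was 797 ± 79.5 against 0.210 ± 0.133 (-11.85 ± 0.26). Of 14 GABAergic genes, 12 were higher in brain, with a median of -10.68 (camera adjusted p = 0.00217; adjusted p = 0.286 with an estimated correlation). Slc32a1, the vesicular GABA transporter gene, was 103 ± 4.36 against 0.0351 ± 0.0447 (-11.35 ± 0.23, or -12.36 without uterus library 4). The 2 members higher in uterus were the homeobox genes Dlx5 (17.3 ± 5.91 against 5.05 ± 0.628, 1.78 ± 0.22) and Lhx6 (18.1 ± 2.44 against 11.7 ± 0.406, 0.62 ± 0.10).

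Of 15 monoaminergic genes, 12 were higher in brain, with a median of -5.37 (camera adjusted p = 0.00455; adjusted p = 0.186 with an estimated correlation). Slc6a3, the dopamine transporter gene, was 14.2 ± 0.449 CPM in brain with 0 counts in uterus, at least 781-fold higher. The monoamine oxidase genes Maob (224 ± 46.2 against 31.0 ± 1.82, 2.85 ± 0.15) and Maoa (111 ± 6.83 against 56.9 ± 4.97, 0.97 ± 0.07) were higher in uterus.

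Glial genes were higher in brain as well. All 12 astrocyte genes were, with a median of -6.86 (camera adjusted p = 9.1e-05; adjusted p = 0.0807 with an estimated correlation). Slc1a2, a glutamate uptake gene, was 2431 ± 129 CPM against 1.85 ± 0.577 (-10.35 ± 0.23), and Aqp4, a water channel gene, was 266 ± 12.6 against 0.0467 ± 0.0659 (-12.33 ± 0.25, or -13.72 without uterus library 4). Of 14 oligodendrocyte genes, 13 were higher in brain, with a median of -8.60 (camera adjusted p = 8.5e-05; adjusted p = 0.0886 with an estimated correlation). Olig2, a transcription factor of the lineage, was 32.0 ± 0.757 CPM with 0 counts in uterus, at least 1756-fold higher, and Cspg4, which pericytes also express, was higher in uterus at 52.4 ± 3.52 against 24.6 ± 1.07 (1.09 ± 0.06).

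The 12 microglial genes were divided, with 7 higher in brain, 4 in uterus and 1, Trem2, that did not pass (7.83 against 9.08 CPM). Their median was -1.27, and the list was not called (camera adjusted p = 0.406; adjusted p = 0.622 with an estimated correlation). P2ry12, a purinergic receptor gene of microglia, was 33.9 ± 1.55 in brain and 1.31 ± 0.268 in uterus (-4.69 ± 0.13), whereas Olfml3 was 223 ± 23.2 in uterus and 19.7 ± 4.16 in brain (3.51 ± 0.14) and Sall1 was 124 ± 17.1 and 31.4 ± 4.27 (1.98 ± 0.12).

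Hypothalamic peptides were detected in whole brain at low to moderate levels. Oxt, the oxytocin gene (ENSMUSG00000027301, chromosome 2, 130576173 to 130577054), was 8.17 ± 0.351 CPM with 0 counts in uterus, at least 448-fold higher. Avp, the neighbouring vasopressin gene (chromosome 2, 130580620 to 130582554), was 8.24 ± 1.497 CPM, a ratio of 678 over 2 uterus counts, both in uterus library 4 (95% interval 188 to 5602; fitted log2 fold change -9.09, or -11.40 without that library), and Crh, a stress hormone gene, was 5.005 ± 0.656 with 0 counts in uterus, at least 275-fold higher. Of 16 tested peptide genes, 14 were higher in brain and Gnrh1 did not pass (1.09 against 0.856 CPM), with a median of -6.01 (camera adjusted p = 0.00123; adjusted p = 0.0886 with an estimated correlation). Tac2, a tachykinin gene, was 12.4 ± 7.26 in uterus and 5.12 ± 0.429 in brain (1.27 ± 0.54, adjusted p = 0.0485). That call rested on the set of libraries and the setting, since it passed only without uterus library 4 among the fits with 1 library left out, and the log2 fold change in the other such fits was 1.08 to 1.33. RLE scaling, a filter of 1 CPM, DESeq2, limma-voom (0.77) and a block for replicate number (0.99) also ended it.

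Receptors for hormones of pregnancy and metabolism went both ways. Prlr, the prolactin receptor gene (ENSMUSG00000005268, chromosome 15, 10177238 to 10349180), was 23.8 ± 5.30 CPM in brain and 7.99 ± 1.72 in uterus (-1.58 ± 0.19, adjusted p = 2.1e-05). Rxfp1, the relaxin receptor gene, was 450 ± 151 in uterus and 23.9 ± 3.46 in brain (4.24 ± 0.23), and Lepr, the leptin receptor gene, was 87.0 ± 19.1 and 7.48 ± 0.621 (3.54 ± 0.16). Crhr1, a receptor gene for Crh, was 42.0 ± 3.82 in brain with 0 counts in uterus, at least 2306-fold higher. Of 16 tested genes, 10 were higher in brain and 4 in uterus, with a median of -2.91, and the list was not called (camera adjusted p = 0.218; adjusted p = 0.30 with an estimated correlation). Avpr1a (1.40 against 1.13 CPM) and Oxtr, the oxytocin receptor gene (9.73 ± 2.46 against 8.10 ± 0.896, 0.27 ± 0.17, adjusted p = 0.168), did not pass, though Oxtr passed under upper-quartile and library-size scaling (0.52 in both).

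**Figure D3:**
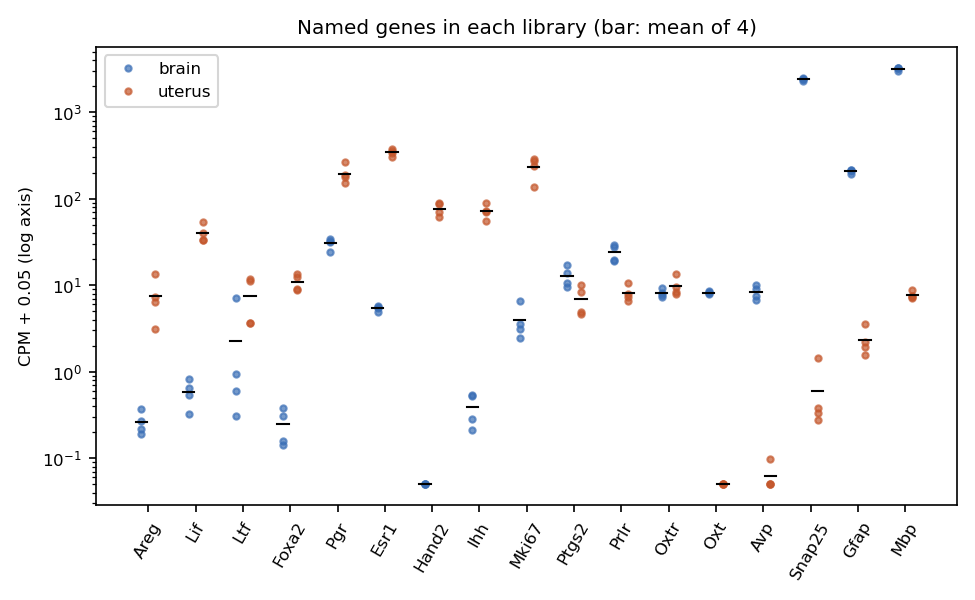
CPM plus 0.05 on a log axis for 17 genes in each of the 4 brain (blue) and 4 uterus (orange) libraries, with the mean of 4 as a bar. Lif was 40 CPM in uterus against 0.536 in brain, Oxt 8.17 in brain against 0 counts in uterus, and the ranges of Ltf, Ptgs2 and Oxtr overlapped.

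Of 15 tested imprinted genes, 11 were higher in brain and 4 in uterus, with a median of -2.77 (camera adjusted p = 0.0390; adjusted p = 0.204 with an estimated correlation). Rasgrf1 and Snrpn, both expressed from the paternal copy, were 430 ± 21.7 and 385 ± 15.2 CPM in brain against 4.15 ± 1.03 and 7.39 ± 0.673 in uterus (-6.70 ± 0.17 and -5.70 ± 0.08). Cdkn1c, a cell cycle inhibitor gene, was 23.4 ± 1.66 in uterus and 3.72 ± 0.401 in brain (2.65 ± 0.10), and Grb10 was 313 ± 12.3 and 82.5 ± 1.81 (1.92 ± 0.05).

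All 18 nuclear genes of oxidative phosphorylation were higher in brain by moderate amounts, with a median of -0.65 (camera adjusted p = 0.000535; adjusted p = 0.322 with an estimated correlation). Ndufs1 and Sdha, genes of respiratory complexes, were 185 ± 8.27 and 483 ± 20.9 CPM in brain against 91.3 ± 3.40 and 243 ± 10.2 in uterus (-1.02 ± 0.05 and -0.99 ± 0.05). Of the 13 mitochondrially encoded genes, 7 were higher in brain and 6 did not pass, with a median of -0.51 (camera adjusted p = 0.216; adjusted p = 0.621 with an estimated correlation). mt-Nd2, mt-Nd5 and mt-Nd1 were 4908 ± 434, 4628 ± 431 and 5702 ± 561 CPM in brain against 2005 ± 267, 2468 ± 135 and 3118 ± 272 in uterus (-1.29 ± 0.11, -0.91 ± 0.08 and -0.87 ± 0.09). The 6 others, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, were lower in 1 library of each organ, as described with the spread between animals.

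Immediate early genes went both ways, with 4 of 13 higher in uterus, 5 in brain and 4 not passing (4 and 4 adjusted over the list alone, where Npas4 was lost). Their median was -0.30 while camera pointed to uterus, and the list was not called (camera adjusted p = 0.869; adjusted p = 0.943 with an estimated correlation). Arc, an activity-regulated gene of neurons, was 160 ± 43.4 CPM in brain and 3.17 ± 2.59 in uterus (-5.65 ± 0.44, or -6.41 without uterus library 2), whereas Fosl2 was 191 ± 21.1 in uterus and 40.4 ± 7.23 in brain (2.24 ± 0.13). Of 15 commonly used reference genes, 7 were higher in each organ. The median was -0.0064, which turned to 0.25 under upper-quartile and library-size scaling, the mean was 0.47, and the list was not called (camera adjusted p = 0.695; adjusted p = 0.809 with an estimated correlation). Rplp0, a ribosomal protein gene with a near-identical copy elsewhere in the annotation, was 1915 ± 145 CPM in uterus and 170 ± 6.41 in brain (3.50 ± 0.08), and Gusb was 98.9 ± 1.81 and 19.4 ± 1.95 (2.35 ± 0.07).

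Markers of tissues that a dissection could carry along ranged widely in level. Both tested pituitary genes were higher in brain, with a median of -3.64 (camera adjusted p = 0.255; adjusted p = 0.349 with an estimated correlation), and Tshb was 3.26 ± 0.278 CPM there. Of 9 choroid plexus genes, 8 were higher in brain and Aqp1 was higher in uterus, with a median of -5.32 (camera adjusted p = 0.0175; adjusted p = 0.30 with an estimated correlation); Ttr, the transthyretin gene, was 791 ± 119 CPM in brain. Of 8 genes of oviduct and cilia, 5 were higher in brain and 2, Pax8 (51.2 ± 7.33 against 0.727 ± 0.250) and Ovgp1 (30.6 ± 16.0 against 6.27 ± 0.472), in uterus, with a median of -4.22 (camera adjusted p = 0.406; adjusted p = 0.478 with an estimated correlation). Of 6 tested ovary genes, 4 were higher in brain, with a median of -2.28 (camera adjusted p = 0.159; adjusted p = 0.281 with an estimated correlation), and Cyp11a1 was 0.270 ± 0.140 CPM in uterus. The embryo list had 1 tested gene, Tdgf1, which was 1.07 ± 0.188 CPM in brain and 0.0806 ± 0.0633 in uterus (-3.70 ± 0.50; camera adjusted p = 0.435; adjusted p = 0.537 with an estimated correlation). Pou5f1, a gene of the pluripotent embryo, had 0 counts in all 8 libraries, so it was not detectable at this depth.

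Of 3 tested genes of cervical and vaginal epithelium, 2 were higher in uterus and Trp63 in brain, with a median of 2.37 (camera adjusted p = 0.572; adjusted p = 0.622 with an estimated correlation). Of 3 adipocyte genes, 2 were higher in uterus and Plin4 in brain, with a median of 0.86 (camera adjusted p = 0.844; adjusted p = 0.850 with an estimated correlation). The call of 1 of them, Car3, a carbonic anhydrase gene (1.38 ± 0.458 against 0.758 ± 0.330 CPM, 0.86 ± 0.34), ended without brain library 1 (0.81), brain library 2 (0.69), brain library 3 (0.83) or uterus library 3 (0.61). With only brain libraries 2 to 4 and uterus libraries 1 and 3, the calls of Trp63 (-0.73), Plin4 (-0.62) and Car3 (0.98) ended. The 6 tested erythroid genes were all higher in brain, with a median of -1.49 (camera adjusted p = 0.305; adjusted p = 0.622 with an estimated correlation), and Hbb-bs, a beta globin gene, was 94.2 ± 41.2 CPM there and 36.0 ± 7.97 in uterus. Limma-voom did not call 1 of the 6, Hba-a2 (-1.69). Of 8 skeletal muscle genes, 5 were higher in uterus and 2 in brain, with a median of 1.71 (camera adjusted p = 0.406; adjusted p = 0.478 with an estimated correlation), and Acta1, an alpha actin gene, was 119 ± 31.2 CPM in uterus. Of 8 genes of enteric and peripheral nerve, 5 were higher in brain and 2 in uterus, with a median of -2.06 (camera adjusted p = 0.435; adjusted p = 0.537 with an estimated correlation), and the myelin gene Pmp22 was 159 ± 13.4 in uterus and 32.1 ± 1.03 in brain. The Y-linked genes Ddx3y, Kdm5d and Uty had 0 counts in all libraries, and Eif2s3y had counts in uterus library 4 alone (0.186 CPM), so the list was not tested.

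The series title relates uterine genes to the maternal brain, and ligands of 1 organ were therefore set beside their receptors in the other. Of 36 pairs fixed beforehand, 11 had a ligand above 2-fold higher in uterus and a receptor detected in all 4 brains. Examples were Lif with its receptor gene Lifr, which was 63.5 ± 3.94 CPM in brain, and Igf1, at 515 CPM in uterus against 12.9 in brain (5.32), with Igf1r, at 104 ± 1.76 in brain. The others were Areg with Egfr, Adm with Calcrl, Edn1 with Ednra, Cxcl12 with Cxcr4, Tgfb1 with Tgfbr1, Il1b with Il1r1, Bmp4 with Bmpr1b, Wnt5a with Ror2 and Pgf with Flt1. In the other direction 10 pairs were found, namely Bdnf with Ntrk2, Oxt with Oxtr, Cx3cl1 with Cx3cr1, Hbegf with Egfr, Igf2 with Igf1r, Igf2 with Igf2r, Inhba with Acvr2a, Il34 with Csf1r, Il33 with Il1rl1 and Apln with Aplnr. Bdnf, a neurotrophin gene, was 30.7 ± 4.37 CPM in brain and 0.672 ± 0.368 in uterus (-5.51 ± 0.30), and its receptor gene Ntrk2 was 59.0 ± 6.78 in uterus and 753 ± 18.9 in brain. The mean level of the receptor was higher in the organ of its ligand in 8 of the 11 pairs with a uterine ligand, among them Wnt5a with Ror2 (45.1 ± 9.08 in uterus, 1.40 ± 0.273 in brain), and in 5 of the 10 others. Co-detection of a ligand and a receptor as RNA does not measure any signal between the organs.

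As a list, 15 of 28 tested ligands were higher in uterus, 10 in brain, and Calca and Edn3 were among those that did not pass, with a median of 0.60 (camera adjusted p = 0.417; adjusted p = 0.622 with an estimated correlation). Of 26 tested receptors, 16 were higher in uterus and 9 in brain (16 and 10 adjusted over the list alone, where Kit was gained), with a median of 0.92 (camera adjusted p = 0.184; adjusted p = 0.351 with an estimated correlation). Aplnr, the apelin receptor gene, was 225 ± 17.5 CPM in uterus and 0.745 ± 0.308 in brain (8.22 ± 0.19).

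Many genes were shared by the organs. At 1 CPM or more in every library, 12316 genes were detected in both organs, 1020 in uterus alone and 1508 in brain alone. Restricted expression was found for 131 genes in uterus and 291 in brain. It depends on its limits, since 40 and 89 genes qualified with 0 counts in the other organ and 46 and 150 at 5 CPM or more. Like levels were found for 2706 genes, of which 1375 still differed by the edgeR test, and 1127 genes qualified with bounds of 0.3. With RLE scaling 2721 genes qualified, and with library sizes 2419. The 5 most abundant were Hspa8, a heat shock chaperone gene (2366 ± 140 CPM in brain, 2881 ± 164 in uterus, 0.28 ± 0.07), the RNA helicase gene Ddx5 (0.33 ± 0.06), Eif4g2 (0.37 ± 0.06), Srrm2 and Hnrnpu (0.31 ± 0.07), and Hspa8 and Ddx5 have near-identical copies. Srrm2, a splicing protein gene, was 983 ± 75.2 in brain and 973 ± 48.5 in uterus (-0.014 ± 0.071, adjusted p = 0.852), and its sign turned under upper-quartile (0.24) and library-size (0.24) scaling and without brain library 4 (0.032), uterus library 1 (0.017) or uterus library 3 (0.011).

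Animals differed more in uterus than in brain, with a coefficient of variation of 16.4% against 9.07%, a difference that was not tested. The most variable genes of both organs lay together on the mitochondrial genome. mt-Co2 (ENSMUSG00000064354, chromosome M, 7013 to 7696), a cytochrome oxidase gene, was 31.5 CPM in brain library 1 and 1198 to 4725 in the other brains, and 939 in uterus library 2 against 1388 to 5529 in the other uteri. mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l dropped in the same 2 libraries, and their log2 fold changes of 0.52 ± 1.45, 0.67 ± 1.42, 0.88 ± 1.46, 0.61 ± 1.25 and 0.28 ± 1.36 did not pass. Those of mt-Nd4l, mt-Nd3 and mt-Co3 turned negative in some alternatives, mt-Nd4l without brain library 1 (-0.12) or uterus library 1 (-0.30) and mt-Co3 without uterus library 1 (-0.042). Without brain library 2 the values rose, to 1.66 for mt-Atp8, 1.48 for mt-Atp6, 1.41 for mt-Co2, 1.20 for mt-Nd3 and 1.05 for mt-Nd4l. In the uterus, the gland genes Prss28, Prss29 and Spink1 were 0.653, 2.28 and 4.90 CPM in uterus library 4, against 21.5 to 222, 46.4 to 559 and 95.8 to 339 in the other 3.

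**Figure D4:**
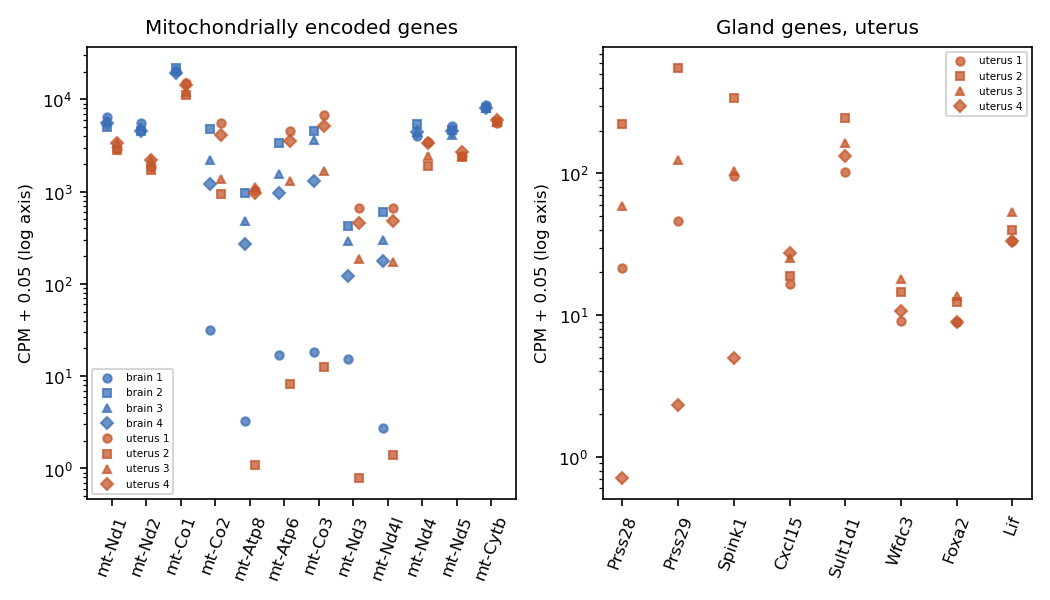
CPM plus 0.05 on a log axis for 12 mitochondrially encoded genes in all 8 libraries (left, ordered along the mitochondrial genome) and for 8 gland genes in the 4 uterus libraries (right), 1 symbol per library. Brain library 1 and uterus library 2 fall at mt-Atp6, mt-Atp8, mt-Co3, mt-Nd3 and mt-Nd4l, and uterus library 4 falls at Prss28, Prss29 and Spink1.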

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

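The tests of the mitochondrial and the gland patterns below were chosen after these results were seen. A value was examined when it stood apart from the other 3 libraries of its organ by a gap of over 0.829 of the whole range of the 4 (log2 scale for genes). The mitochondrial genes other than mt-Atp8 and the gland genes Prss28, Prss29 and Spink1 did not meet this limit and are given because of their spread. Of 326 groups of 4 values examined, 21 did so, 17 of 245 for genes, 4 of 75 for lists and 0 of 6 for library measures, and chance alone gives about 1 in 20.

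The first pattern is a fall in the counts of neighbouring mitochondrially encoded genes in brain library 1 and uterus library 2. In uterus library 2, mt-Atp8 was 1.03 CPM against 966 to 1134 in the other uteri, and 5 genes with a near-identical annotated copy over 90% or more of their length (mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) were lower in both libraries, by log2 differences from -1.75 to -8.95. Fewer mitochondrial transcripts in these libraries are excluded as the cause, since the 5 genes with no copy at all, mt-Atp8 left out as part of the pattern, had a median log2 difference of 0.0596 (SD 0.212, from -0.30 to 0.38). Reads shared with the copies, which lie on chromosome 1 (24611535 to 24616197), stay open as a candidate explanation: over the 13 mitochondrially encoded genes, the mean spread was 3.44 in these 5 and 0.669 in the others (exact one-sided permutation p = 0.00466), but 2.52 in the 7 with a copy of any length and 0.820 in the others (p = 0.0670). Against it, mt-Nd4, with a copy over 63.6% of its length, lay at -0.24 in brain library 1 and -0.67 in uterus library 2, mt-Co1 (31.3%) at -0.047 and -0.30, and mt-Atp8, with no copy found, fell in both; the handling of reads with several places is not given here, and no biological explanation was tested.

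The second pattern is the low level of 3 secreted gland products in uterus library 4, where Prss28, Prss29 and Spink1 lay -6.55, -5.98 and -4.93 on the log2 scale from the mean of the other uteri. Fewer gland cells in that library are excluded as the whole cause, since the 8 other gland genes had a median difference of -0.294 (SD 0.586, from -1.40 to 0.47). Reads shared with annotated copies of 98% identity over at least 150 nt are excluded as well, since 0 of the 3 genes had one. Copies outside the annotated transcripts, and shorter or less alike ones, were not searched and stay open. Uterus library 4 also stood apart with low Tac2 (1.56 CPM against 14.9 to 17.2) and low Fgf9 (2.52 against 6.65 to 7.41). The design names no group that differs in it, and no biological explanation was tested.

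The other values stand without explanation. In brain library 4, Htr2c was 91.8 CPM (84.1 to 85.0 in the others), Col3a1 8.96 (7.13 to 7.33) and Cdh5 17.7 (19.9 to 20.2). Brain library 1 held Eef1a2 at 820 CPM (913 to 924), Olig1 at 97.7 (110 to 112) and Siglech at 16.4 (12.9 to 13.1). For Slc32a1 brain library 3 had 110 CPM (101 to 102). Ttr was 613 CPM in brain library 2 (844 to 863). In uterus, Snrpn was 8.39 CPM in library 4 (6.998 to 7.13), while library 2 had Arc at 7.06 (1.82 to 1.91) and Hbb-bs at 24.2 (37.9 to 41.1). Mean deviations of lists on the log2 scale stood apart for steroid receptors in uterus library 4 (0.144), for ligands in brain library 4 (-0.0944), for the pituitary list in brain library 2 (-0.456) and for skeletal muscle in brain library 1 (-0.164).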

How the results depend on the processing

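The fit with only brain libraries 2 to 4 and uterus libraries 1 and 3 was chosen after the data were seen; all other settings were fixed before. Counts of called genes moved from 13989 to between 13149 (threshold of 0.01) and 14781 (no low-count filter), and the 2-fold count from 7922 to between 7352 (DESeq2) and 8494 (no low-count filter). The reduced set of libraries called 13985 genes, 8044 of them past the 2-fold test. Scaling moved the balance more: 57.8% of called genes were higher in uterus with upper-quartile scaling and 57.9% with library sizes, against 49.95% in the reported fit. With 1 library left out, called genes numbered 13818 to 14044, those past the 2-fold test 7918 to 8009, called lists 22 in every fit, genes detected in both organs 12324 to 12391, restricted genes 130 to 153 in uterus and 292 to 349 in brain, and genes at like levels 2517 to 2662.

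The counts that moved by over 1.5 times did so with a stricter limit or with another setting or test for the lists. A stricter limit lowers a count by construction, while the cause of the change in list calls was not tested. With 0 counts required in the other organ, 40 genes were restricted to uterus and 89 to brain, and at 5 CPM or more 46 and 150. With bounds of 0.3, 1127 genes were at like levels. Camera with an estimated correlation called 0 lists and fry 36, against 22. The spread between uteri, which is not among these counts, was 13.8% for genes at 10 CPM or more, against 16.4%.

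Of 165 named genes tested, 164 kept their direction and side of the threshold with RLE scaling or DESeq2, 159 with upper-quartile or library-size scaling, 156 with limma-voom and 160 to 165 with 1 library left out. Of 39 lists, 38 or 39 did so with RLE or library-size scaling, a prior count of 0.5, the block, 1 library left out or the reduced set of libraries, 17 with the estimated correlation and 25 with fry. Directions turned for genes and lists near 0 or with a large spread, and the cause was not tested. Srrm2 turned to 0.24 with both upper-quartile and library-size scaling and ranged from -0.042 to 0.032 with 1 library left out. With limma-voom mt-Nd4l turned to -0.11 and mt-Nd3 to -0.65, and with 1 library left out mt-Nd4l ranged from -0.30 to 1.05 and mt-Co3 from -0.042 to 1.05. The immediate early genes, never called, changed direction with library sizes (adjusted p = 0.954) and without brain library 4 or uterus library 1. Over all fits with 1 library left out, the adjusted p of the list immediate early genes was 0.792 (without brain library 2) to 0.984 (without uterus library 1). The adipocyte list, never called by camera, changed direction in 4 of those 8 fits (0.823 to 0.976 over all 8) and in the reduced set of libraries (adjusted p = 0.725).

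A block for replicate number was tried although the labels do not pair the animals; it gave 13846 genes, 7878 past the 2-fold test, 22 lists and 2678 genes at like levels. Pairing by number changed the calls of Tac2, which was lost (0.99), and Ltf, which passed (2.48), and turned the immediate early genes (adjusted p = 0.977). Over all tested genes, libraries with the same number correlated at -0.048 to 0.083 after the organ means were removed, against -0.084 to 0.10 for other numbers, and 4 of 8 libraries correlated best with their own number. DESeq2 gave no adjusted p for 10 genes. Depth limits the large folds, since a gene with 0 counts in an organ could still be present at up to 3 counts there; 40 and 89 of the restricted genes are of this kind.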

Other observations

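The groupings by symbol in the next 2 paragraphs, the test of the numbers of replicates and that of one animal per number were chosen after the result was seen, while the test for shared reads and the splits of the libraries were planned before.

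Genes were grouped by the stem of their symbol into 17 groups, of which camera called 8, or 2 with an estimated correlation. The 8 kept their direction under RLE, upper-quartile and library-size scaling. Of 79 ribosomal protein genes, 78 were higher in uterus, with a median log2 fold change of 2.31 (camera adjusted p = 7.6e-17; adjusted p = 0.202 with an estimated correlation), and Rps18 was 1060 ± 80.8 CPM in uterus against 131 ± 3.53 in brain. Integrin genes were higher in uterus in 20 of 31 cases (median 1.64; adjusted p = 0.00508, and 0.0539 as adjusted p with an estimated correlation), and Itgb1, a subunit shared by many integrins, was 730 ± 10.9 against 95.2 ± 3.67. Chemokine genes were higher in 19 of 26 (median 2.85; adjusted p = 0.00576, and 0.150 as adjusted p with an estimated correlation), and Cxcl17, with 0 counts in brain, was 29.5 ± 2.23 CPM, at least 1633-fold higher. The replication helicase gene Mcm3 was 104 ± 9.99 CPM against 3.15 ± 0.225. Of 10 genes with the symbol stem Mcm, 9 were higher in uterus (median 3.38, camera adjusted p = 0.00217, and 0.202 as adjusted p with an estimated correlation). The exception, Mcm3ap, was 78.1 CPM in brain and 67.8 in uterus. Guanylate-binding genes, which interferon induces, were higher in uterus in 8 of 9 cases (median 3.09; adjusted p = 0.00508, and 0.207 as adjusted p with an estimated correlation).

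Brain held the higher level for 72 of 86 potassium channel genes, with a median of -4.61 (camera adjusted p = 3.6e-08; adjusted p = 0.0162 with an estimated correlation). Kcnj10, a potassium channel gene of glia, was 372 ± 36.3 CPM in brain and 0.338 ± 0.136 in uterus. GABA-A receptor subunits were higher in brain in 15 of 17 cases, with a median of -7.96 (camera adjusted p = 4.9e-05; adjusted p = 0.0276 with an estimated correlation), and 1, Gabrp, was higher in uterus at 4.68 ± 3.70 CPM. Protocadherins were higher in brain in 59 of 65 cases, with a median of -1.92 (camera adjusted p = 6.6e-08; adjusted p = 0.0539 with an estimated correlation), and Pcdh9 was 184 ± 3.90 against 2.20 ± 0.573. The 9 groups not called (adjusted p 0.0533 to 0.996) were frizzled genes, serpins, solute carriers, claudins, histones, keratins, Zfp genes, aquaporins and Wnt genes. The medians of Zfp and Wnt genes turned with library sizes, from -0.019 to 0.24 and from -0.26 to 0.00073.

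A small set of genes varied between animals in both organs, and their deviations went with the replicate number. Over the 40 genes with an SD of log2 CPM above 0.5 in both organs, deviations of brain and uterus libraries with the same number correlated across genes at -0.042, 0.79, 0.67 and 0.57, and 1 of the 24 ways to match the numbers, the given one, reached its mean of 0.497, with 0.438 the highest of the others. Chance matching stays open, since 1 of 24 is the smallest share this test can give and it was chosen after the values were seen. Reads shared with copies stay open, because 21 of 39 searched genes had a near-identical copy (53.9%, against 8.50% of 200 random genes) and the 18 without one had a mean correlation of 0.299, which 3 of the 24 ways reached. Over the 21 genes with a copy the mean correlation was 0.691, which 1 of the 24 ways, the given match, reached. Organs of one animal under one number may be a candidate explanation that stays open, with 6 of 8 libraries correlating best with their own number and brain library 1 unmatched. Ide, an insulin-degrading enzyme gene on chromosome 19 (37268743 to 37337852), shows the pattern, at 140, 70.9, 138 and 73.4 CPM in brain libraries 1 to 4 and 186, 88.6, 195 and 91.6 in uterus libraries 1 to 4.

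Other ways to split the 8 libraries into equal groups were fitted, 35 with the real one. For the called genes, 1 of the 35 splits, the real one, gave 13989 and the highest other gave 0. For the 2-fold test 1 split, again the real one, gave 7922 and the highest other 0. A share of 1 of 35 is the smallest that this test can give. All other splits mix the organs within a group, so their 0 does not show how many calls chance alone would give. For genes at like levels, 19 of the 35 splits gave as many as the real 2706, with 2866 the highest other, and for list calls 10 splits gave as many as the real 22, with 25 the highest other. These 2 counts followed how many libraries were exchanged: splits with 2 libraries of each organ in each group gave 2724 to 2866 genes and 0 to 4 lists, and splits with 3 and 1 gave 2224 to 2288 genes and 18 to 25 lists. Since both counts varied with the mix of organs in a split, the splits do not decide on chance for either.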
